A study of Mus musculus with 10 samples.

How the data were processed

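RNA was measured in 10 libraries of sorted splenic mouse plasma cells, 5 of IgM and 5 of IgG1 cells, grouped by their sample titles. Per the labels' protocols, total RNA was extracted with the miRNeasy Micro kit, and libraries came from Takara's SMART-Seq mRNA HT LP kit, which amplifies full-length cDNA from small inputs and does not keep strand. Per the submitters' processing notes, the authors used HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffdiff, with the mouse build GRCm38, and the roles, settings and annotation release are not given in the sources used here. Per the file headers, the deposited values are FPKM, fragments scaled by transcript length and by the mapped fragments of the library, in 1 file per library keyed by Ensembl gene identifier. No scaling across libraries is stated. FPKM is a share of each library, so genes that take much of it lower the rest. Short segments such as immunoglobulin J segments can take very large values: Iglj1 was at 0 in 5 libraries and reached 465240 FPKM in another, and sums of FPKM ran from 1333417 to 1934268. An exact 0 can also be a failed estimate. No pair of files held identical values.

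All 47719 identifiers were joined, and 47305 matched GENCODE release M21, which is on GRCm38 and gave symbols, gene types and coordinates. The other 414 kept their identifiers. Coordinates are counted from 1.

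Depth was estimated from the steps between low FPKM values of genes with 1 transcript, since for a given gene 1 fragment adds a smaller step in a deeper library. The main estimate came from the lowest values, assuming a mean fragment of 200 bases, and a comparison of steps between libraries differed from it by at most 0.613%. With 100 or 400 bases assumed, IgG1 replicate 2, the deepest library, came to 35340000 or 43280000 fragments instead of 37870000. On values simulated with the same 200 bases that the estimate assumes, the largest error was 0.0601%, which does not test that assumption. These depths give relative precision and no counting interval.

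Genes with a mean of at least 1 FPKM over all libraries were tested on log2 of FPKM plus a pseudocount of 1 with limma 3.58.1 in R 4.3.3, with trend and robust settings, group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Log2 differences are IgG1 minus IgM on that scale, which understates changes of low genes. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 3 measured genes. Calls were repeated with an estimated correlation and with fry, which tests whether a list's genes move on balance one way without comparing it with other genes. Counts of members passing were also adjusted over the list alone. Shares and library measures were compared with two-sided exact permutation tests of the difference in means in scipy 1.17.1, which with 252 arrangements cannot go below 0.00794. Their p-values were adjusted over 12 measures. Tables used pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9, in Python 3.11.15.

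Named genes followed a rule fixed beforehand. It took the 12 genes with the largest difference in each direction among those that passed, with no overlap between groups and a mean of at least 5 FPKM in the higher group, leaving out immunoglobulin genes and gene models without a proper symbol. It also took the constant region genes, up to 4 members of every list by smallest p, or 2 by level where none passed, and Prdm1, Xbp1, Irf4, Sdc1, Tnfrsf17, S1pr2 and S1pr1. This gave 160 genes, of which part are named. Genes named only to say which members of a list went the other way were chosen after their values were seen.

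On simulated data for this comparison over 9900 genes, with 50 genes changed at each size, the test recovered 46% of genes changed 1.5-fold, 74% at 2-fold, 94% at 3-fold and 96% at 4-fold, with 9 false calls. These are folds of FPKM plus 1, so for low genes the simulated change in FPKM itself was larger. For lists, 10 of 10 shifted by 0.3 were recovered and 0 of 20 unshifted ones were called. The simulated genes varied independently of each other, so that result does not cover lists whose genes vary together.

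Alternatives planned beforehand were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio scaling, a common total without immunoglobulin genes, quantile normalization, eBayes without trend or robust, array weights, a replicate block, each library left out in turn, and other definitions of the shares. Removing trends with transcript length and GC content (natural splines, 4 degrees of freedom each, per library, with values for 99.8% of tested genes), leaving out IgG1 replicates 4 and 5, leaving immunoglobulin genes out of the list tests and leaving out J and D segments were chosen after the data were seen. No library was left out of the main tests. The labels give no batch, so none was modelled.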

Results

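Splenic plasma cells that carried a germinal centre fate mark were profiled by RNA-seq as 2 sorted groups, 5 libraries of IgM cells and 5 of IgG1 cells. The donor B cells carried S1PR2-CreERT2, a tamoxifen-inducible Cre active in germinal centre B cells, the Ai14 reporter, which turns on tdTomato after Cre acts, and the germline form of B1-8, a heavy chain that binds the hapten NP when paired with a lambda light chain. Wild-type recipients of these cells received the NP-coupled protein CGG in alum on day 0 and tamoxifen on days 5 and 6, and labelled donor plasma cells were taken on day 10. The comparison asks how donor plasma cells with the same fate mark differ with the isotype they express. The groups also differed in kappa and heavy chain variable transcripts, so a difference between them need not follow isotype alone. Sequencing depth, estimated from the smallest steps between low FPKM values, ran from 26610000 to 30890000 fragments in the IgM libraries and from 26160000 to 37870000 in the IgG1 libraries. Although the IgG1 libraries were not shallower on average, with replicate 1 alone below every IgM library, 15487 ± 312 genes were listed above 0 in IgM and 13564 ± 266 in IgG1 libraries (mean ± SD, n = 5 each, two-sided exact permutation p = 0.00794, adjusted p = 0.00952 over 12 library measures). That p is the smallest that 5 against 5 libraries can give. No label says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

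Heavy chain transcripts separated the groups as sorted, with a larger share of other isotypes in the IgM libraries. Ighm made up 77.0% ± 4.93 of heavy chain constant region FPKM in IgM and 1.23% ± 0.151 in IgG1 libraries (SD, n = 5 each). Ighg1 made up 13.3% ± 3.29 of heavy chain constant region FPKM in IgM libraries and 97.8% ± 0.277 in IgG1 libraries (SD, n = 5 each), a difference of 84.5 percentage points (two-sided exact permutation p = 0.00794, adjusted p = 0.00952). Ighm, the mu constant gene (chromosome 12, 113418558 to 113422730, minus strand, GRCm38), stood at 85377 ± 3310.0 FPKM in IgM and 1170.3 ± 85.5 FPKM in IgG1 cells (SD, n = 5; log2 difference -6.19, SE 0.04, adjusted p = 3.60e-23). Ighg1 (chromosome 12, 113325240 to 113330523, minus strand) stood at 14974 ± 4280.0 FPKM in IgM and 93807 ± 8149 FPKM in IgG1 cells (log2 difference 2.70, SE 0.20, adjusted p = 1.36e-05). The Ighg1 level in IgM libraries was thus 16.0% of that in IgG1 libraries, whereas the Ighm level in IgG1 libraries was 1.37% of that in IgM libraries. The paired version of the test of the Ighg1 share cannot go below 0.0625.

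Most other constant region genes were also higher in IgM cells. Of the 13 measured constant region and J chain genes, 10 were lower and 1 (Ighg1) was higher in IgG1 cells, with 1 higher and 10 lower adjusted over the list alone and a median log2 difference of -2.14 (camera adjusted p = 6.35e-06, and adjusted p = 0.0865 with an estimated correlation). Mean FPKM in IgM against IgG1 cells was 4879 against 276 for Ighg2b, 1899 against 147 for Ighg2c, 1624 against 217 for Ighg3, 1056 against 134 for Igha and 1336 against 118 for Ighe. Reads of these closely related genes can be shared among them, so each value is uncertain. Igkc, the kappa light chain, was at 53697 ± 12970.0 against 17330.0 ± 2422 FPKM (log2 difference -1.61, adjusted p = 1.34e-04). Kappa made up 11.9% ± 2.39 of light chain constant FPKM in IgM and 4.78% ± 0.427 in IgG1 libraries (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.00952). Iglc1, the most abundant lambda gene, differed less (log2 difference -0.20, adjusted p = 0.0098), and its call ended with eBayes without trend or robust (adjusted p = 0.0618). The call of Iglc2 ended without a filter (adjusted p = 0.0601), without IgG1 replicates 4 and 5 (adjusted p = 0.112, chosen after seeing the data) and without any of 8 single libraries, all but IgM replicates 2 and 3 (adjusted p = 0.0614 to 0.0867). Jchain, which joins antibody polymers, was at 38835 ± 1595 against 21143 ± 1531 FPKM (log2 difference -0.88, adjusted p = 4.55e-09). The calls of these 3 genes were also absent under quantile normalization, but it keeps only ranks and so is no test of them, since in every library Iglc1 ranked 1 or 2, Iglc2 11 to 13 and Jchain 7 or 8 among the tested genes. All immunoglobulin genes together took 73.6% ± 1.81 of summed FPKM in IgM and 69.8% ± 4.72 in IgG1 libraries (SD, n = 5 each, exact permutation p = 0.143, adjusted p = 0.143). The difference of −3.83 percentage points came to −2.37 without IgG1 replicate 2 (exact permutation p = 0.286). Short joining segments took large and unequal values in some libraries. Without J and D segments, an alternative chosen after seeing the data, the shares were 69.9% ± 1.42 and 63.2% ± 0.996 (SD, n = 5 each, exact permutation p = 0.00794).

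**Figure D1:**
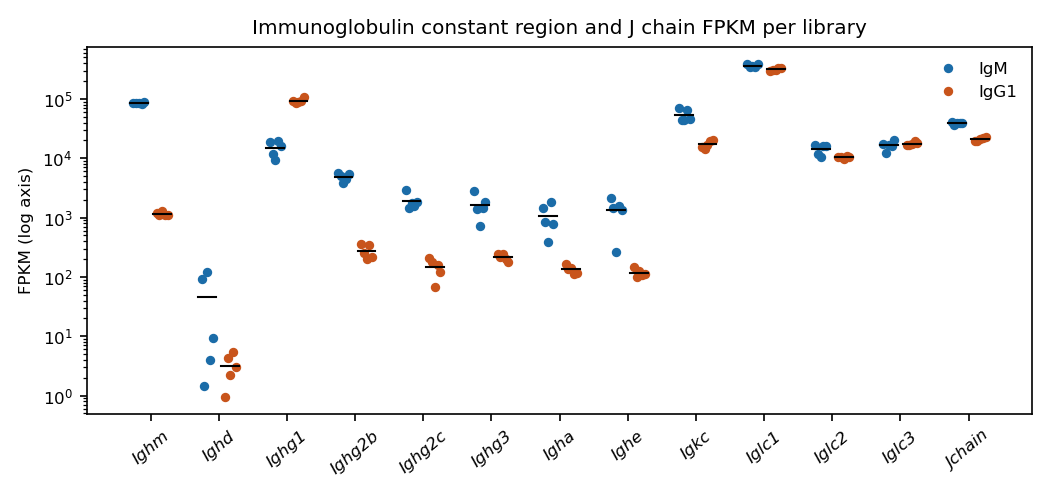
FPKM of immunoglobulin constant region genes and the J chain on a log axis, with 1 point per library (5 IgM in blue, 5 IgG1 in orange) and a black bar at the group mean. Ighm was at a mean of 85377 in IgM and 1170 in IgG1 libraries, and Ighg1 stood higher in every IgG1 library than in any IgM library.

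The groups differed in a large part of the transcriptome. Pycard, the inflammasome adaptor ASC, was about 3 times as high in IgG1 cells, and Bcl2l11, the pro-death protein Bim, was lower in IgG1 cells by more than 5 times. Among 9900 genes with a mean of at least 1 FPKM, 3792 passed the test, 1791 of them higher and 2001 lower in IgG1 cells (limma, Benjamini-Hochberg adjusted p under 0.05). In 2538 of these genes the 5 IgG1 values did not overlap the 5 IgM values. Over all tested genes, 26.3% did not overlap, where chance gives 0.794%. With quantile normalization the split was 2182 higher and 1510 lower, and the median log2 difference over all genes was 0.06 in place of −0.05. With a common total without immunoglobulin genes it was 1474 higher and 2415 lower, with a median of −0.12, so the balance between higher and lower genes depends on the scaling. With an added requirement of an absolute log2 difference of at least 1, there were 107 higher and 504 lower.

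Genes that led the higher side in IgG1 cells included a homing integrin and an inflammasome adaptor. Itgb7 (chromosome 15, 102215995 to 102231944, minus strand), the beta 7 integrin subunit that takes part in homing to mucosal sites, stood at 8.95 ± 2.61 against 34.0 ± 4.22 FPKM (IgM against IgG1, mean ± SD, n = 5 each; log2 difference 1.84, SE 0.16, adjusted p = 9.86e-08). Pycard (chromosome 7, 127989708 to 127993867, minus strand) stood at 113 ± 6.00 against 343 ± 31.6 FPKM (log2 difference 1.59, SE 0.07, adjusted p = 1.02e-11). Tmem238, a membrane protein, was at 2.68 ± 0.774 against 12.5 ± 1.19 FPKM (log2 difference 1.897, adjusted p = 1.71e-07). The nuclear envelope gene Nrm was at 8.71 against 25.6 FPKM and the nuclear pore gene Nup210 at 17.9 against 50.7 FPKM. Uhrf1, which maintains DNA methylation at replication forks, was at 10.2 ± 3.33 against 27.8 ± 3.97 FPKM (log2 difference 1.40, adjusted p = 4.85e-06). The histone chaperone Npm3 was at 7.33 against 22.8 FPKM, the histone gene Hist3h2ba at 3.56 against 10.5, the lipid transporter Abca3 at 3.24 against 9.95, the nucleotide hydrolase Dnph1 at 1.34 against 5.55, the peptidase Thop1 at 2.60 against 7.90 and the inositol synthesis enzyme Isyna1 at 14.0 against 36.6. The log2 differences of these 12 genes ranged from 1.35 to 1.897.

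Genes on the lower side in IgG1 cells moved further. Hdac9 (chromosome 12, 34047580 to 34917095, minus strand), a class II histone deacetylase, stood at 19.7 ± 2.74 against 1.03 ± 0.456 FPKM (IgM against IgG1, mean ± SD, n = 5 each; log2 difference -3.37, SE 0.19, adjusted p = 5.28e-10). Bcl2l11 (chromosome 2, 128126038 to 128162547, plus strand) stood at 160.2 ± 13.9 against 29.4 ± 2.01 FPKM (log2 difference -2.41, SE 0.08, adjusted p = 2.91e-13). Malat1, a nuclear long noncoding RNA, stood at 3410.3 ± 482 against 515 ± 137 FPKM (log2 difference -2.75, SE 0.19, adjusted p = 7.64e-06). The activation genes Fos and Egr1 were at 79.2 against 9.97 and 16.6 against 1.35 FPKM. Egr2 was listed at 0 in every IgG1 library and at 4.95, 6.51, 12.4, 7.78 and 6.15 FPKM in the IgM libraries. The adaptor Samsn1 was at 62.1 against 9.46 FPKM, the lipoprotein Apoe at 83.1 against 12.1, the inhibitory receptor Btla at 10.8 against 0.981, the splicing-related gene Pnisr at 53.8 against 8.78, the amino acid oxidase Il4i1 at 7.74 against 0.577 and Ccdc17 at 19.3 against 3.05. The log2 differences of these 12 genes ranged from -3.37 to -2.40.

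**Figure D2:**
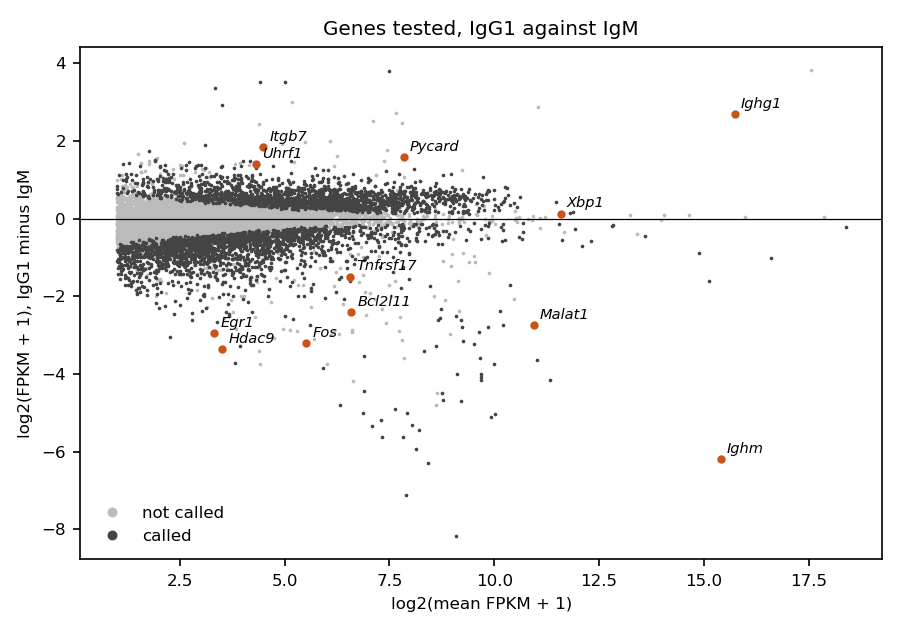
Log2 difference (IgG1 minus IgM, on log2 FPKM plus 1) of the 9900 tested genes against the log2 of their mean FPKM plus 1, with called genes in dark grey and some named genes in orange. The points reach further below 0 than above it, with 504 called genes lower and 107 higher by at least 1.

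Of 39 gene lists fixed before the data were examined, 32 had at least 3 measured genes, and 19 differed between the groups, 7 higher and 12 lower in IgG1 cells (camera with a preset correlation of 0.01). With an estimated correlation 2 of the 19 calls held, those of plasma cell identity and of glycolysis. Plasma cell identity genes were lower in IgG1 cells, although the secretory regulator Xbp1 was not. Of 22 measured members, 18 were lower and 1 higher, with 1 higher and 19 lower adjusted over the list alone (camera adjusted p = 1.36e-07, and adjusted p = 0.00823 with an estimated correlation). Tnfrsf17, the survival receptor BCMA, was at 138 ± 9.71 against 48.3 ± 3.79 FPKM (IgM against IgG1, SD, n = 5 each; log2 difference -1.49, SE 0.08, adjusted p = 1.42e-10). Prdm1, the regulator Blimp-1, was at 53.5 ± 2.71 against 29.2 ± 2.70 FPKM (log2 difference -0.86, SE 0.09, adjusted p = 6.37e-07). Slamf7 was at 388 against 258 FPKM and Edem1 at 1391 against 938. Smaller differences were measured for Irf4 (log2 difference -0.24, adjusted p = 0.0496) and for Sdc1, the marker CD138 (log2 difference -0.13, adjusted p = 0.0468). Xbp1 was at 2928 ± 124 against 3194 ± 116 FPKM (log2 difference 0.13, adjusted p = 0.0104). The calls of Xbp1, Irf4 and Sdc1 each ended under several alternatives. That of Irf4 ended without any of IgM replicates 1, 2, 3 and 5 or IgG1 replicates 2, 3 and 4 (adjusted p = 0.0565 to 0.126), and that of Sdc1 without any of IgM replicates 1, 2, 3 and 5 or IgG1 replicates 2, 3 and 5 (adjusted p = 0.0535 to 0.118). The replicate block also ended the call of Sdc1 (adjusted p = 0.0697). Xbp1 turned to −0.05 once trends with transcript length and GC content were removed.

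Endoplasmic reticulum folding genes were mostly lower in IgG1 cells, while the transport machinery went both ways. Of 35 unfolded protein response and chaperone genes, 21 were lower and 3 higher, with 4 higher and 21 lower adjusted over the list alone (median -0.19, camera adjusted p = 2.73e-05, and adjusted p = 0.0865 with an estimated correlation). Txndc5, a disulfide isomerase, was at 2029 ± 95.6 against 618 ± 33.4 FPKM (SD, n = 5 each; log2 difference -1.71, SE 0.04, adjusted p = 9.16e-15), and the chaperone partners Dnajc3 and Dnajb9 were at 294 against 182 and 256 against 169 FPKM. Of 44 secretory transport genes, 12 were higher, among them the translocon subunits Sec61g (849 against 1195 FPKM) and Sec61b (1217 against 1605), and 16 lower, among them Sec63 (115 against 80.1) and Ssr3 (389 against 294). The list as a whole did not pass (camera adjusted p = 0.862), with 12 higher and 16 lower adjusted over the list alone. Of 30 glycosylation genes, 6 were higher and 9 lower (camera adjusted p = 0.862), with 6 higher and 9 lower adjusted over the list alone. Stt3b, a catalytic subunit of oligosaccharyltransferase, was at 159 against 76.0 FPKM and the sialyltransferase St6gal1 at 299 against 199.

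Activation genes were lower in IgG1 cells than in IgM cells. Of 16 immediate early genes, 13 were lower and 1, Myc, was higher, with 1 higher and 14 lower adjusted over the list alone (median -1.31, camera adjusted p = 3.85e-06, and adjusted p = 0.0865 with an estimated correlation). Zfp36, which binds AU-rich mRNAs, was at 140.2 ± 19.6 against 45.03 ± 3.94 FPKM (SD, n = 5 each; log2 difference -1.61, adjusted p = 5.28e-10). The phosphatase Dusp5 was at 14.7 against 4.36 FPKM and Nfkbia, the inhibitor of NF-kB, at 64.1 against 32.2. Beside this, heat shock genes, which handling can raise among other causes, went the other way. Of 10 measured members, 6 were higher and 1 lower in IgG1 cells, with 6 higher and 1 lower adjusted over the list alone (median 0.47, camera adjusted p = 0.0221, and adjusted p = 0.204 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.0525) and without IgG1 replicate 1 (adjusted p = 0.0522). Hspe1 was at 74.1 against 129 FPKM and Hspa8 at 290.0 against 440.0.

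Genes of the B cell stage were lower in IgG1 cells, in part. Of 18 mature B cell genes, 10 were lower and 1, Cd37, was higher, with 1 higher and 10 lower adjusted over the list alone (median -0.55, camera adjusted p = 0.00622, and adjusted p = 0.0865 with an estimated correlation). The transcription factor Ets1 was at 27.1 ± 1.64 against 15.6 ± 0.976 FPKM (log2 difference -0.76, adjusted p = 1.39e-05), Ms4a1 (CD20) at 62.9 against 42.9 and Cxcr5, a follicle homing receptor, at 2.95 against 0.265. Of 13 MHC class II genes, 5 were lower and 1 higher (camera adjusted p = 0.0661), with 1 higher and 5 lower adjusted over the list alone. H2-Ob was at 54.9 against 22.1 FPKM, and Cd74, at 6102 against 4093, turned to a log2 difference of 0.15 under quantile normalization, which is no test of its level, as it ranked 15 to 18 among the tested genes in every library. Of 13 germinal centre genes, 5 were lower (camera adjusted p = 0.0614), with 0 higher and 5 lower adjusted over the list alone, and Gcsam was at 14.6 against 4.21 FPKM. Of 27 receptor signalling genes, 5 were higher and 12 lower (camera adjusted p = 0.0614), with 5 higher and 12 lower adjusted over the list alone. The adaptor Sh3bp2 was at 16.5 against 3.31 FPKM and the phosphatase Ptpn6 at 48.1 against 16.1. The MHC class II, germinal centre and receptor signalling lists lay close to the threshold, and each passed under 6 or 7 settings, among them a common total without immunoglobulin genes (camera adjusted p = 0.0431, 0.0450 and 0.0449) and the removal of length and GC trends (0.00751, 0.0134 and 0.00973, chosen after seeing the data). Without IgM replicate 1 the MHC class II (0.0300) and germinal centre lists (0.0342) passed, and without IgG1 replicate 4 the germinal centre list (0.0461).

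Receptors that restrain or instruct B lineage cells were also lower in IgG1 cells. Of 12 inhibitory and Fc receptor genes, 8 were lower and 1, Siglecg, was higher, with 1 higher and 8 lower adjusted over the list alone (median -0.59, camera adjusted p = 0.00265, and adjusted p = 0.0865 with an estimated correlation). Fcmr, the receptor for IgM, was at 38.4 ± 10.6 against 8.62 ± 1.35 FPKM (log2 difference −1.999, adjusted p = 7.53e-08) and Cd200 at 5.66 against 0.374. Of 24 cytokine receptor and STAT genes, 10 were lower and 1 higher, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.0333, and adjusted p = 0.0865 with an estimated correlation). That call ended without IgG1 replicate 1 (adjusted p = 0.0523). Il2rb was at 12.8 against 3.18 FPKM and Il13ra1 at 17.2 against 3.78. Of 20 interferon response genes, 8 were lower and 2 higher (camera adjusted p = 0.0509), with 2 higher and 8 lower adjusted over the list alone. That list passed under 11 settings, among them the replicate block (camera adjusted p = 0.0481) and the omission of IgM replicate 1 (0.0342), IgM replicate 4 (0.0304) or IgG1 replicate 5 (0.0260). Of 18 subset transcription factors, 5 were lower and 1 higher (camera adjusted p = 0.0897), with 1 higher and 5 lower adjusted over the list alone, and the list passed without a filter (adjusted p = 0.0218), at a mean of 5 FPKM (0.0383) and with fry (7.03e-04). Of 16 B-1 and marginal zone genes, 4 were higher, Vim among them at 12.1 against 28.2 FPKM, and 6 lower (camera adjusted p = 0.862), with 6 higher and 7 lower adjusted over the list alone. None of the 3 measured cytokine genes passed, Ebi3 standing at 25.7 against 29.3 FPKM and Ltb at 14.1 against 12.02 (camera adjusted p = 0.974), with 0 higher and 0 lower adjusted over the list alone.

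Replication, ribosome and energy genes were higher in IgG1 cells. Of 34 DNA replication genes, 29 were higher and 0 lower, with 31 higher and 0 lower adjusted over the list alone (median 0.67, camera adjusted p = 1.73e-15, and adjusted p = 0.0865 with an estimated correlation). The helicase subunits Mcm5 and Mcm7 were at 37.7 against 91.3 and 38.6 against 80.4 FPKM, and Rrm2, which makes deoxynucleotides, was at 261 ± 22.3 against 445 ± 17.9 (log2 difference 0.77, adjusted p = 1.61e-08). Of 30 G2 and mitosis genes, 15 were higher and 1, Cenpf, was lower, with 16 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.12e-04, and adjusted p = 0.192 with an estimated correlation). The kinase Plk1 was at 32.7 against 66.2 FPKM. All 76 ribosomal protein genes were higher, with 76 higher and 0 lower adjusted over the list alone (median 0.61, camera adjusted p = 2.95e-43, and adjusted p = 0.0865 with an estimated correlation), and Rps2 was at 549.9 against 1147 FPKM. Of 69 nuclear genes of oxidative phosphorylation, 65 were higher and 0 lower, with 66 higher and 0 lower adjusted over the list alone (median 0.47, camera adjusted p = 2.58e-28, and adjusted p = 0.0865 with an estimated correlation). Uqcrc1, a subunit of complex III, was at 101 against 239 FPKM. Beside these 2 lists, short transcripts ran higher in IgG1 cells and long ones lower, with a median log2 difference of 0.21 in the shortest of 5 equal bins of protein-coding genes and −0.24 in the longest.

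Glycolysis genes were higher in IgG1 cells as well, with 11 of 21 members higher and 0 lower and 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.73e-05, and adjusted p = 0.0256 with an estimated correlation). Eno1 and Ldha were at 159 against 384 and 203 against 395 FPKM. Of 25 amino acid and integrated stress response genes, 13 were higher and 4 lower, with 13 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00622, and adjusted p = 0.0865 with an estimated correlation). The serine synthesis genes Phgdh, Psph and Shmt2 were at 156 against 273, 24.4 against 42.4 and 52.3 against 102 FPKM. Mitochondrially encoded genes went the other way, with 6 of 13 lower in IgG1 cells and 0 higher and 6 lower adjusted over the list alone (median -0.37, camera adjusted p = 0.00622, and adjusted p = 0.257 with an estimated correlation). With the length and GC trends removed, that median was −0.04 and the call ended (adjusted p = 0.309). Beside it, mt-Co1 was at 720 FPKM in IgG1 replicate 4 and 721 in replicate 5, against 1163 to 1230 in the other IgG1 libraries. Without these 2 libraries, an alternative chosen after seeing the data, 3175 genes and 22 lists passed. Of 23 cholesterol synthesis genes, 5 were higher and 4 lower (camera adjusted p = 0.66), with 5 higher and 4 lower adjusted over the list alone.

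**Figure D3:**
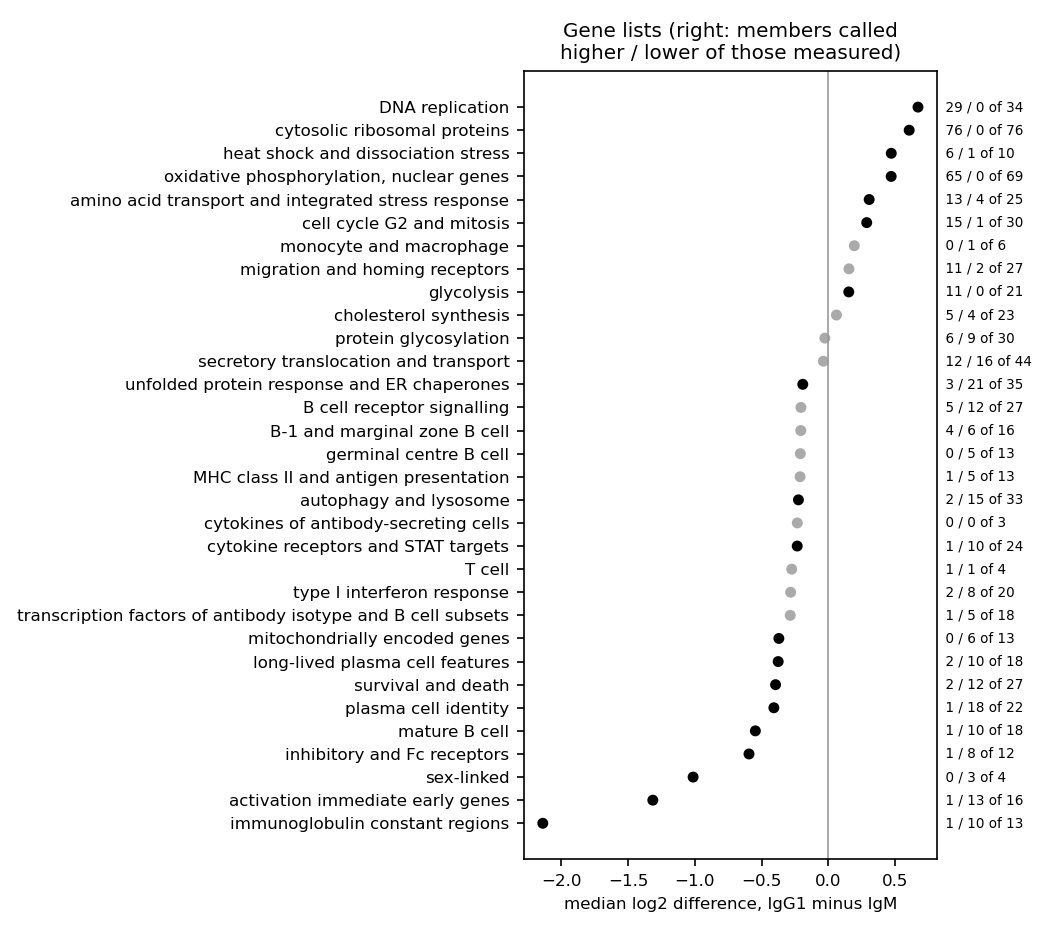
Median log2 difference (IgG1 minus IgM) over the measured members of each of 32 gene lists, black where the list passed camera at the preset correlation and grey where it did not, with members called higher and lower at the right. Ribosomal proteins, with 76 of 76 members higher, lie to the right of 0 and immediate early genes, with 13 of 16 lower, to the left.

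Survival genes were lower in IgG1 cells on both sides of the balance between survival and death. Of 27 measured members, 12 were lower and 2 higher, with 2 higher and 12 lower adjusted over the list alone (median -0.39, camera adjusted p = 0.0072, and adjusted p = 0.0906 with an estimated correlation). The lower members held the pro-death gene Bcl2l11 and Casp8, which starts receptor-driven death (53.9 against 31.8 FPKM), as well as Birc2, an inhibitor of apoptosis (47.3 against 22.9 FPKM), and Tnfrsf17. Of 18 genes linked to long-lived plasma cells, 10 were lower and 2 higher, with 2 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.00622, and adjusted p = 0.0865 with an estimated correlation). Zbtb20 was at 43.3 ± 6.90 against 13.7 ± 3.84 FPKM (log2 difference -1.62, adjusted p = 6.15e-07) and Slc3a2 at 182 against 102. Of 33 autophagy and lysosome genes, 15 were lower and 2 higher, with 2 higher and 16 lower adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.205 with an estimated correlation), and Lamp2 was at 101 against 56.2 FPKM. Of 27 migration genes, 11 were higher and 2 lower, with 11 higher and 3 lower adjusted over the list alone and no call for the list (camera adjusted p = 0.0661). Cd44 was at 58.4 against 78.8 FPKM and Cd93 at 15.6 against 8.65. S1pr2, whose promoter drove the mark, was at 8.57 ± 1.21 against 8.50 ± 2.32 FPKM (log2 difference -0.04, adjusted p = 0.897), and S1pr1, which guides exit into blood, at 14.0 ± 4.23 against 13.7 ± 1.02 (log2 difference 0.03, adjusted p = 0.916).

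**Figure D4:**
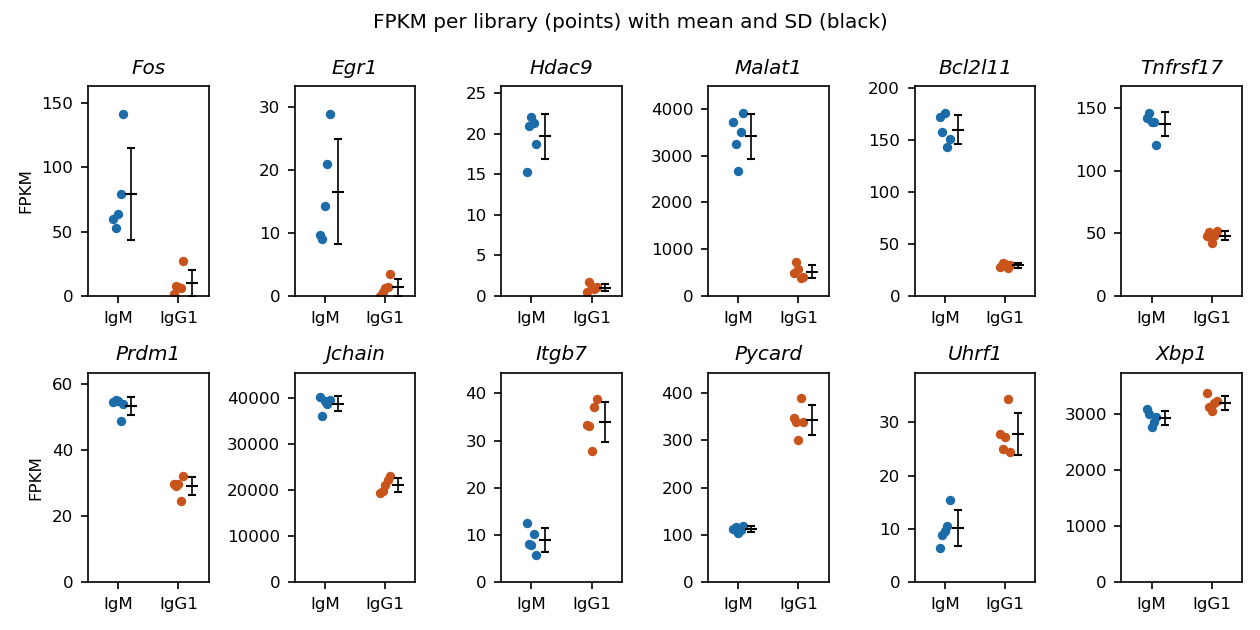
FPKM per library of 12 named genes, with 1 point per library (5 IgM in blue, 5 IgG1 in orange) and the mean and SD in black. Bcl2l11 had a mean of 160.2 in IgM and 29.4 in IgG1 libraries, and Pycard of 113 and 343.

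Of the lists of other cell types, 2 had at least 3 measured genes, and neither passed. Of 4 measured T cell genes, Cd4 was higher at 0.280 against 1.87 FPKM and Trac lower at 2.37 against 0.201 (camera adjusted p = 0.834), with 1 higher and 1 lower adjusted over the list alone. Of 6 monocyte and macrophage genes, 1, Cd68, was lower at 31.2 against 12.9 FPKM (camera adjusted p = 0.974), with 0 higher and 1 lower adjusted over the list alone. Apoe, a transcript of macrophages among other cells that is outside the list, was at 83.1 against 12.1 FPKM. The median of the list was 0.20 while fry gave the opposite direction (adjusted p = 0.0993). Fewer than 3 genes were measured for 7 lists. The highest mean over the 10 libraries was 1.61 FPKM for NK cells (Prf1), 0.268 for neutrophils (Ly6g), 0.879 for the red cell lineage (Hbb-bs), 0.801 for platelets (Itga2b), 0.326 for basophils and mast cells (Kit) and 5.95 for stroma and endothelium (Pecam1). Of the dendritic cell genes, Bst2, which plasma cells also express, was at 141 FPKM. Y-linked genes were lower in IgG1 cells, with 3 of 4 measured sex-linked genes called lower and 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00622, and adjusted p = 0.0865 with an estimated correlation). Ddx3y was at 32.4 ± 3.62 against 11.1 ± 2.15 FPKM (log2 difference -1.47, adjusted p = 1.26e-07). The X-linked Xist, on the same list but too low to be tested, was at 0 in every IgG1 library and at most 0.162 FPKM in an IgM library.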

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

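All tests of explanations below were chosen after the results they bear on had been seen. Each of 339 groups of 5 values was checked for a library far from the others. Chance marks about 1 in 20 groups, here 16.9, and 19 were marked, so the number is close to that by chance. IgG1 replicate 5 was marked for Thop1 (9.22 FPKM, others 7.38 to 7.77), Fos (27.0, others 1.45 to 7.98), Nfkbia (47.1, others 25.8 to 30.8), Ddx58 (30.5, others 22.7 to 24.5) and Klrk1 (0.832, others 0). IgG1 replicate 1 was marked for Il4i1 (1.46, others 0.321 to 0.436), Cxcr5 (0.923, others 0 to 0.221), Trac (0.696, others 0 to 0.185) and Pf4 (2.36, others 0). IgG1 replicate 3 was marked for Uty (7.01, others 3.56 to 4.19) and replicate 4 for Madcam1 (0.0493, others 0). IgM replicate 1 was marked for Ighg2c (2880 FPKM, others 1472 to 1827) and Klrk1 (0.605, others 0 to 0.0117), IgM replicate 2 for Man1a2 (47.9, others 37.3 to 40.1), Lgals1 (124, others 140.0 to 145) and mt-Cytb (1782, others 1920.3 to 1968), IgM replicate 4 for Prdm1 (48.7, others 54.0 to 55.3), and IgM replicate 5 for Tnfrsf17 (121, others 139 to 146) and Ly6g (0.659, others 0). The calls of Fos, Thop1, Il4i1, Nfkbia, Ighg2c, Tnfrsf17, Man1a2, Prdm1 and mt-Cytb were kept without each library in turn.

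Median differences of lincRNA, antisense and TEC genes and of long transcripts lay toward IgM cells, and ribosomal protein and oxidative phosphorylation mRNAs were higher in IgG1 cells. Genomic DNA in the IgM libraries would give silent genes about the same gain as noncoding ones, but over all 226 measured genes of these classes, called or not, the median gain was at least 70.8 times the mean gain of silent olfactory and vomeronasal genes in every IgM library, which argues against it for genes of at least 1 FPKM. For the larger number of genes above 0 it stays open, since the lowest IgM library exceeded the highest IgG1 library in the share of silent genes above 0 by 1.23 percentage points. A length and GC trend as the whole cause is argued against by 95.0% of the called ribosomal and oxidative phosphorylation genes passing after its removal. The medians of these 2 lists were then 0.50 and 0.41, against 0.077 left in the shortest bin of genes. Dilution by nuclear RNA should have moved chaperone mRNAs with the ribosomal ones, yet their median was −0.19. That list cannot decide, since it may differ between the isotypes for other reasons. The lincRNA genes (median −0.54) lay in the direction that dilution needs, so it stays open. A biological difference between the isotypes may remain as a hypothesis, untested here.

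Transcripts of other heavy chain isotypes, kappa chains and varied VH genes were higher in IgM libraries. IgG1 cells in the IgM sort are argued against as their source, since Ighg2b, Ighg2c, Ighg3, Igha and Ighe stood at no less than 46.9 times the level that the Ighg1 share predicts, while the Ighg1 signal itself was left open. Reads shared with Ighg1 would make the other gamma genes follow it, yet the lowest IgM library held at least 3.04 times the highest IgG1 library for Ighg2b, Ighg2c and Ighg3. The sort took tdTomato-labelled donor plasma cells, a gate that should remove host and unlabelled ones. Plasma cells that passed it in error, or free RNA, may still be a candidate source. Kappa was higher and Ighv1-72, the VH gene of B1-8, took a smaller share of VH FPKM in every IgM library than in any IgG1 library. The smaller gap was 4.48 percentage points. These shares restate the pattern, so they are no test of that source. Ighv1-72 took 47.0% of VH FPKM in IgM and 67.0% in IgG1 libraries, and a wider receptor repertoire among donor cells was not tested.

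Immediate early genes were higher in IgM cells. Stronger heat stress in IgM cells during handling should have raised heat shock genes there. Their list instead had a median of 0.47, higher in IgG1 cells. That list cannot decide, since it may differ between the isotypes for other reasons, and its call ended under some settings. A handling response limited to immediate early genes was not tested. The sort for plasma cells should remove mature B cells, but mature B cells that passed it into the IgM group cannot be told apart from a difference in plasma cells: their list had a median of −0.55, in the direction needed, but smaller than that of the immediate early genes, and Pax5 and Cd22 lay under 1 FPKM on average in both groups. A biological difference between the isotypes was not tested.

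Of 100 splits of the 10 libraries drawn from 126, 1, the real one, gave as many as 3792 genes. The highest of the others gave 1. Every other split mixed the isotypes on both sides, so a difference between them widens the spread within sides and keeps counts low. The count thus went with the sorted grouping of these libraries, but the gap to 1 does not measure its strength. Chance between animals or pools was not tested, since no label says that the libraries came from separate animals. For the lists, 2 of 100 splits gave 19 or more, the real one included, and the highest of the others also gave 19, with 0 genes. That share is under 0.05, but list calls at the preset correlation also arose without the real grouping: 96 of the 99 other splits gave at least 1 list, with a median of 4. The 21 splits that kept 4 of the 5 libraries of each group together gave 11 to 19 lists, and the other 78 gave 0 to 10, so a single list call at that setting is weak evidence.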

How the results depend on the processing

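The removal of length and GC trends, the omission of IgG1 replicates 4 and 5, of immunoglobulin genes from the list tests, and of J and D segments were tests chosen after the data were seen. The count of 3792 genes stayed between 2818 and 3889 under the other settings of normalization, filter and model, and between 3428 and 3578 with each library left out, and came to 611 with an absolute log2 difference of at least 1, a stricter requirement by construction. The count of 19 lists was 17 to 22 with each library left out and 19 to 23 under the other settings of normalization, filter, model and genes with camera at the preset correlation, the 23 arising without a filter, at a mean of 5 FPKM and with a common total without immunoglobulin genes. It was 27 with fry (8 higher and 19 lower), and 2 with an estimated correlation. The estimates reached 0.478 for ribosomal protein genes and 0.268 for oxidative phosphorylation genes, far above the preset 0.01. For plasma cell identity and glycolysis, whose calls held, they were −0.00875 and 0.00571. The cytokine receptor list lost its call at 0.000498, so its own correlation does not account for that, and the reason was not tested. Of 13 lists without a call, 8 passed under some setting, among them T cell genes (adjusted p = 0.0171) and glycosylation (0.00193) under fry alone, and migration under fry (0.00299) and without a filter (0.0338). Of 8 named genes without a call, Ltb passed with trends removed (0.0218) and Prf1 under quantile normalization (0.0259). The replicate block gave 3701 genes, 20 lists, a difference of −3.83 percentage points in the immunoglobulin share (exact sign-flip permutation p = 0.125) and 84.5 in the Ighg1 share (p = 0.0625, the lowest that 5 pairs allow). With each gene's group mean subtracted, the deviations of same-numbered libraries correlated at −0.0357 to 0.0966. Not every library's deviations correlated best with those of its own number, so the numbers were not treated as pairs.

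The immunoglobulin share differed by −6.69 percentage points without J and D segments and passed. Apart from Cd74 and Xbp1, directions turned only in lists and genes with no call: without a filter for secretory transport (adjusted p = 0.857), glycosylation (0.903) and B-1 genes (0.857), under quantile normalization for cytokines (0.946) and B-1 genes (0.846), at a mean of 5 FPKM for B-1 genes (0.936), and for monocyte genes at a pseudocount of 5 (0.962), with array weights (0.994), fry (0.0993), trends removed (0.808) and without IgG1 replicates 4 and 5 (0.984). With libraries left out, lists that turned at least once had adjusted p of 0.735 to 0.986 for secretory transport, 0.857 to 0.998 for cytokines, 0.683 to 0.995 for B-1 genes, 0.270 to 0.876 for T cell genes and 0.857 to 0.995 for monocyte genes. Log2 differences turned to 0.148 for Cd74, 0.107 for S1pr2 (quantile), 0.00420 for S1pr2 (array weights), −0.0434 for S1pr1 (common total), and, with trends removed, −0.0670 for Ebi3, −0.0518 for Xbp1 and −0.00969 for S1pr1. With a library left out they ran from −0.00379 to 0.188 for Iglc3, −0.151 to 0.0543 for S1pr2 and −0.156 to 0.139 for S1pr1. The cause was not tested. Of 142 called named genes, 12 lost the call or turned under some setting. Of simulated genes changed 1.5-fold in FPKM plus 1, 4 of 23 below the median level and 19 of 27 above it were recovered, so low genes are the harder ones to call. Depth was not varied.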

Other observations

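Of 88 measured lincRNA genes, 35 were called lower and 3 higher in IgG1 cells, and 50 were not called (median log2 difference −0.54). The share called lower was 39.8%, against 20.2% of all tested genes. Of 115 antisense genes, where the reads of partner genes are mixed in without strand, 24 were called lower and 3 higher and 88 were not called, so the share called lower, 20.9%, was close to that of all genes, while 2.61% were called higher against 18.1% of all genes. Neither class was tested for enrichment. Neat1, which builds nuclear paraspeckles, was at 27.5 ± 1.26 against 5.61 ± 1.68 FPKM (log2 difference -2.15, adjusted p = 1.67e-08), a gene chosen after its values were seen. Processed pseudogenes went the other way, with 44 of 171 higher and 16 lower (median 0.39), and share reads with their parent genes. Called chemokine receptors, in part chosen after their values were seen, went both ways. Cxcr3 was higher in IgG1 cells at 4.14 ± 1.60 against 10.1 ± 2.33 FPKM (log2 difference 1.14, adjusted p = 6.52e-04), as were Ccr10 (log2 difference 0.88, adjusted p = 0.00284) and Cxcr4 (log2 difference 0.50, adjusted p = 0.014), and Cxcr5 was lower at 2.95 ± 1.19 against 0.265 ± 0.382 FPKM (log2 difference -1.62, adjusted p = 2.60e-04).

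Libraries correlated at 0.926 to 0.945 within IgM, 0.956 to 0.965 within IgG1 and 0.901 to 0.921 between the groups (Pearson r across genes, which are not independent replicates). The first principal component held 37.8% of the variance and parted the groups. On the second, with 11.9%, IgM replicates 2 and 3 lay at −30.0 and −32.6, and the other IgM libraries between 5.35 and 27.9. Mitochondrially encoded mRNA took 1.19% ± 0.0288 of FPKM outside immunoglobulin genes in IgM and 0.831% ± 0.113 in IgG1 libraries (SD, n = 5 each, exact permutation p = 0.00794). Mki67 stood at 43.2 ± 4.63 against 36.4 ± 3.72 FPKM (log2 difference -0.24, adjusted p = 0.0625) and so did not pass, although 29 of 34 replication genes were higher in IgG1 cells.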
